A study of Homo sapiens with 2 samples.

How the data were processed

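Poly(A) RNA was measured in 2 libraries of human ureteric bud organoids grown from the induced pluripotent stem cell line 1231A3. The ureteric bud is the epithelial outgrowth of the nephric duct that branches into the collecting ducts of the kidney. Day 6 organoids were incubated for 2 h with DiI-VLDL, a very low density lipoprotein carrying a fluorescent lipid dye, dissociated and sorted by flow cytometry. Per the labels, 1 library holds DiI-VLDL positive cells and 1 holds DiI-VLDL negative cells. The labels give no replicate of either group. The title of the negative library is NC, and its group was taken from the status label and the extraction protocol, which name sorted negative cells. Cells without dye served as gating controls, per the labels, and whether the NC library is such a control is not settled by the sources used here.

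The authors deposited a table of gene counts for both libraries, with the exon coordinates, gene type and merged exon length of each gene. The counts of the authors are whole numbers per gene and are not normalised, per the file headers and the values. The genome build is GRCh38, per the submitters' processing notes. The aligner, the settings of the counting program, the handling of strand and the annotation release are not given in the sources used here. The table lists 63353 genes, of which 5611 lie on alternate scaffolds. A read could be counted at more than 1 gene: TUBB has 8 rows, and 5 of its 7 scaffold rows carry the same count in the positive library as the chromosome row (4168). The totals are therefore sums of counts, not of distinct reads, and genes with near-identical copies are uncertain.

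The authors also deposited a comparison table for 33149 genes, which are as many as the genes with at least 1 read. It holds a baseMean score, a log2 fold change of positive over negative cells, its standard error and Wald statistic as a score, and a p-value with its adjusted p-value, per the file headers. DESeq2 1.20.0 is named in the submitters' processing notes. For the 15949 genes with at least 20 reads in both libraries, the deposited log2 fold change differed by at most 0.00052 from the log2 ratio of the deposited counts under median-of-ratios size factors computed with DESeq2 1.42.0, so it was not shrunken.

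The total count was 13092281 in the positive and 18282529 in the negative library. Counts were scaled to CPM (counts per 1e6 counts of a library) with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.983 and 1.02. Further steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. For each gene, the ratio of scaled CPM, positive over negative, is given with an exact Clopper-Pearson 95% interval from the binomial split of its reads. With 1 library per group no test of the conditions is possible, no difference has a replicate check, and no p-value was computed. The intervals and floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

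A fixed rule of size took the place of a test: a gene was counted as higher or lower where its mean scaled CPM over both libraries was at least 1 and its ratio was at least 2-fold. Where 1 library had no read, 0.5 read stood in for it in log2 ratios, and folds are given as bounds against a floor of 3 counts per library, which is 0.233 scaled CPM in the positive and 0.161 in the negative library. The rows of a symbol on chromosomes were used for named genes and gene lists, and the most abundant one where several shared a symbol, which left 18699 symbols past the filter.

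For each of 36 gene lists fixed before the data were examined, the median log2 ratio of the members past the filter was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 libraries. About 1.8 of 36 lists would lie outside percentiles 2.5 to 97.5 by chance, if genes within a list varied independently, as in the random lists. Where they vary together, that number does not hold. Lists share genes, and 665 distinct genes of the 795 listed were measured. The 95% range of a list median comes from 1000 binomial redraws of its members' reads. In 17 lists a member had no read in 1 library, and setting such members at the floor's bound altered the median of 0 of the 36 lists.

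Genes were named by a rule fixed before the data were examined. It takes 25 key genes whatever their values, the 12 genes with the highest lower interval bound and the 12 with the lowest upper bound among genes with a symbol and a mean scaled CPM of at least 10, and, per list, the 2 members with the highest and the 2 with the lowest ratio. Genes outside it, such as TUBB, TIMM10, MALAT1 and those of the second mesenchyme list, were chosen after their values were seen. Some genes that the rule selects are not reported here. For scale, the rank of a gene's ratio among the 500 genes nearest in mean CPM is given; this measure was added after the data were seen. A set of 395 genes of 11 housekeeping families, such as mitochondrial ribosomal proteins, proteasome subunits and respiratory chain subunits, was also added after the first look at the ratios. Extreme ratios of 2 of its members, MRPL58 and TIMM10, had been seen by then and led to the choice of these families; the values of the set had not been computed.

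The steps were tested on simulated Poisson counts drawn from the mean expression of the 63353 genes and the totals of both libraries, with 200 genes altered by known folds. The median estimated fold was 1.49, 2.03, 3.02 and 3.99 for true folds of 1.5, 2, 3 and 4, and 0, 62, 100 and 100% of these genes were at least 2-fold apart. Of 19771 unaltered genes with a mean scaled CPM of at least 1, 107 were at least 2-fold apart, and 0 of 11364 at a mean of at least 10. Of 40 random lists of 20 unaltered genes, 1 lay outside percentiles 2.5 to 97.5. Simulated counts hold counting error only, and the housekeeping genes scattered far more, so these rates do not carry over to the 2 libraries.

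Alternatives planned before the data were examined were DESeq2 size factors, total counts with and without the most abundant and mitochondrially encoded genes, no filter and a filter at 10 CPM, log2(CPM + 1), a thinned deeper library, folds of 1.5 and 4, intervals wholly beyond 2-fold, unmatched random lists and lists without shared members. Added after the data were seen were chromosome rows only, protein-coding genes only, a filter at 50 CPM, a correction for gene length and GC content, scaling to the housekeeping families, and random lists of housekeeping genes or of abundant genes. GC content came from GENCODE release 29 transcripts, matched by gene identifier, and 93.5% of the genes past the filter had a value; no coordinates were taken from it.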

Results

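Gene expression was compared between sorted DiI-VLDL positive and DiI-VLDL negative cells of day 6 human ureteric bud organoids, with 1 library per group. The labels describe the dye-labelled lipoprotein as a means to sort tip cells, so the comparison addresses which genes of the ureteric bud tip, of the trunk and of lipoprotein metabolism differ between cells that did and did not take up the particle. Reads were found for 31070 genes in the positive and 23479 genes in the negative library, although the negative library was the deeper. Genes with 1 to 3 reads numbered 5918 in the positive and 1321 in the negative library, while genes with at least 10 reads were similar in number, at 20663 and 20832. The negative library is titled NC, and it was taken as sorted negative cells from its status label; if it were cells without dye, the ratios below would not compare 2 sorted fractions. No difference below has a replicate check, and the intervals cover counting error only.

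Lists of ureteric bud tip, ERK target, cell cycle, fatty acid synthesis and mesenchyme genes had higher medians in the DiI-VLDL positive library. Those of collecting duct and epithelial junction genes had lower ones. Within the mesenchyme list, VIM and COL1A2, both abundant, were lower. Of 20011 genes with a mean scaled CPM of at least 1, 3446 (17.2%) were at least 2-fold higher in the positive library and 4028 (20.1%) were at least 2-fold lower. At a mean of at least 10 CPM the numbers were 1221 and 983 of 11566, and at 50 CPM 282 and 193 of 4829. The spread of the ratio was large and depended on abundance. Genes of 11 housekeeping families, such as mitochondrial ribosomal proteins and proteasome subunits, had a robust SD of the log2 ratio of 0.80 at a mean of 10 to 30 CPM, where simulated counting error gave 0.12. These 395 housekeeping genes also had a median log2 ratio of 0.34, with 81 at least 2-fold higher and 2 at least 2-fold lower in the positive library. Scaling the libraries to them gave 2367 genes higher and 5590 lower, so that the share of higher genes among both was 29.7% in place of 46.1%. The medians of 10 of the 36 gene lists have another sign under that scaling, and those of 9 lists under at least 1 other alternative.

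**Figure D1:**
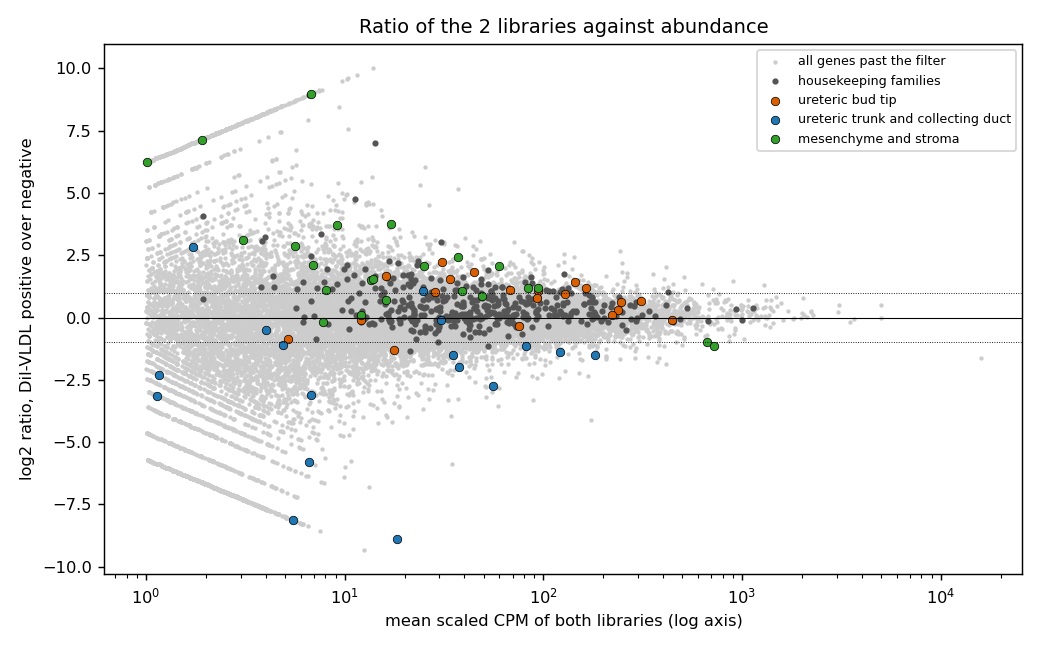
Log2 ratio of scaled CPM, DiI-VLDL positive over negative, against the mean scaled CPM of both libraries on a log axis, 1 point per gene with a mean of at least 1. Dotted lines mark 2-fold. Tip genes lie mostly above 0, trunk and collecting duct genes mostly below it, and the scatter of all genes widens towards low abundance; oblique rows of points are genes with no or few reads in 1 library.

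Genes of the ureteric bud tip, the compartment that responds to GDNF and branches, were higher in DiI-VLDL positive cells. Of 20 measured members, 9 were at least 2-fold higher, 10 lay within 2-fold and 1 was at least 2-fold lower. The median log2 ratio was 0.87 (95% counting range 0.79 to 0.93), above all 10000 matched random lists (central 95% -0.27 to 0.37). WNT11, a tip ligand, was 3.56-fold higher (95% interval 3.15 to 4.03), from 70.1 scaled CPM in the positive against 19.7 in the negative library. SOX8, a transcription factor downstream of RET, was 2.95-fold higher (2.58 to 3.39). GFRA1, the GDNF co-receptor, was 2.28-fold higher. RET, the GDNF receptor, was 1.72-fold higher (1.60 to 1.86), and its ratio ranked at 89.2% among genes of like abundance, whereas WNT11 ranked at 99%. ETV5 was 2.10-fold, SOX9 1.59-fold and ETV4 1.24-fold higher; under the housekeeping scaling ETV4 is not higher. Of the 20 members, 3 lay above and 2 below the central 95% of housekeeping genes of like abundance, with RET, GFRA1, SOX8, SOX9, ETV4 and ETV5 inside it. SLCO4C1 and ADAMTS18 had the lowest ratios of the list, at 2.50-fold and 1.83-fold lower.

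Genes of the ureteric trunk and collecting duct, the more mature compartment, were lower in DiI-VLDL positive cells. Of 17 measured members, 13 were at least 2-fold lower, 2 lay within 2-fold and 2 were at least 2-fold higher, with a median log2 ratio of -1.52 (counting range -1.75 to -1.45; percentile 0.01, matched lists -0.62 to 0.59). ELF5, an epithelial transcription factor, had 1 read against 682, and was 472-fold lower (95% interval 84.4 to 18669). AQP2, the vasopressin-regulated water channel, had 0 reads against 204. It was at least 47.1-fold lower against the floor of 3 counts (lower end of the 95% interval 37.9). The keratin KRT19 was 2.84-fold lower (2.67 to 3.03), from 94.8 against 269 scaled CPM. The trunk ligands WNT9B and WNT7B were 8.69-fold and 8.77-fold lower, the latter from 3 against 38 reads. HSD11B2, which protects the mineralocorticoid receptor from cortisol, was 2.10-fold higher and SCNN1G, a sodium channel subunit, 7.04-fold higher, the latter from 39 against 8 reads. Of the 17 members, 14 lay below that housekeeping range and 0 above it. For members of low abundance such as WNT9B the range was -0.48 to 4.42 in log2 ratio. MUC1, 1.40-fold lower, therefore counted as below, while SCNN1G lay inside, so the counts below and above are not comparable. Housekeeping genes were few at low abundance (2 at 1 to 3 CPM, 24 at 3 to 10 CPM), so low members were set against more abundant ones.

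Genes of the nephric duct and ureteric bud lineage as a whole were also lower in the positive library, with 4 of 16 at least 2-fold lower, 12 within 2-fold and a median of -0.67 (percentile 0). PAX8 was 3.16-fold lower, and CDH16, from 8 against 36 reads, 3.11-fold lower. The lineage transcription factors PAX2 (1.60-fold), GATA3 (1.81-fold) and LHX1 (1.30-fold) were lower in the positive library. HOXB7 and TFAP2B had the highest ratios, at 1.53-fold and 1.45-fold higher. Epithelial junction and polarity genes had a median of -0.98 (percentile 0), with 11 of 23 at least 2-fold lower and 0 at least 2-fold higher. CDH1, the epithelial cadherin, was 3.09-fold lower (2.96 to 3.23), TJP3 was 5.43-fold lower and EPCAM 1.58-fold lower, while PARD3 was 1.51-fold and OCLN 1.08-fold higher. The junction list shares 1 gene with the trunk list.

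ERK pathway targets, which receptor tyrosine kinases such as RET and FGF receptors induce, had a median log2 ratio of 1.10 (percentile 100), with 13 of 20 at least 2-fold higher and 0 at least 2-fold lower. The list shares 6 genes with the tip list. The phosphatase DUSP5 had 250 reads against 0, and FOSL1 had 145 against 0. Against the floor of 3 counts they were at least 120-fold and 69.8-fold higher (lower ends of the 95% intervals 97.2 and 56.1). EGR1 was 1.44-fold lower and CCND1 1.01-fold lower. Cell cycle genes were higher as well. The S phase list had a median of 0.75, with 16 of 42 members at least 2-fold higher and 0 lower, and the G2 and M phase list one of 0.82, with 14 of 54 higher and 1 lower (percentile 100 for both). The exonuclease EXO1 was 3.83-fold and the flap endonuclease FEN1 3.34-fold higher, CCNE2 was 1.56-fold and SLBP 1.54-fold lower. CDK1, the mitotic kinase, was 5.12-fold and TTK 4.47-fold higher, CDC25C was 2.89-fold lower and CDCA2 1.07-fold higher. Above the housekeeping range lay 4 of 20 ERK targets, 5 of 42 S phase genes and 6 of 54 G2 and M phase genes. That range reaches further above 0 than below it. Cytosolic ribosomal protein genes had a median of 0.33 (percentile 99.96; 1 of 74 at least 2-fold higher, RPS28), which is close to that of the housekeeping families; RPL32 was 1.89-fold higher, RPL34 1.37-fold and RPL22 1.21-fold lower.

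Genes of cholesterol synthesis under SREBP2 control were moderately higher in DiI-VLDL positive cells. Their median log2 ratio was 0.53 (counting range 0.47 to 0.60; percentile 99.96, matched lists -0.20 to 0.33), with 3 of 25 members at least 2-fold higher, 22 within 2-fold and 0 at least 2-fold lower. Relative to the housekeeping families the median was 0.19, and it lay at percentile 94.9 of random lists of housekeeping genes, so the list did not stand apart from them. HMGCS1 was 1.61-fold (1.56 to 1.67), SQLE 1.37-fold and INSIG1 1.32-fold higher. PMVK had the highest ratio (2.64-fold), and TM7SF2 (1.39-fold) and MVK (1.31-fold) were lower. Fatty acid synthesis genes had a median of 0.83 (percentile 100; 99.8 among random lists of housekeeping genes), with 6 of 16 at least 2-fold higher and 1 at least 2-fold lower. The malic enzyme ME1 had 107 reads against 0. It was at least 51.5-fold higher against the floor of 3 counts (lower end of the 95% interval 41.2). SCD5 was 7.13-fold higher, ACACB was 2.23-fold lower and GPAM 1.12-fold lower.

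Lipoprotein receptors and uptake genes did not stand apart from genes of like abundance, with a median log2 ratio of -0.17 (counting range -0.31 to -0.10; percentile 13.3), 2 of 24 at least 2-fold higher, 17 within 2-fold and 5 at least 2-fold lower. VLDLR, the receptor named for the particle, was 1.47-fold lower, at 33.3 against 49.0 scaled CPM. Its ratio ranked at 19.4% among genes of like abundance and lay inside the housekeeping range. LRP2, an endocytic receptor of kidney epithelia, was 2.25-fold lower and lay below that range. LRP10 was 2.22-fold higher, LPL 7.27-fold lower and APOB 3.46-fold lower, from 10 reads each in the positive library. Against random lists of housekeeping genes the same median lay at percentile 0. LXR target genes had a median of -0.39 (percentile 8.98; APOC1 18.8-fold higher from 26 against 2 reads, LPCAT3 1.68-fold higher, APOE 3.16-fold and SMPDL3A 2.59-fold lower). Lipid droplet and PPAR target genes (median -0.10, percentile 38.8), lysosomal genes (-0.07, percentile 29.4) and endocytosis machinery (0.10, percentile 63.3) lay inside the range of matched lists. Of the lipid droplet genes, PLIN5 had 76 reads against 1 and FABP5 was 4.69-fold higher, CPT1A was 3.61-fold lower. Of the lysosomal genes, TFEB had 32 reads against 0, GUSB was 4.12-fold higher, GAA 1.97-fold and CTSL 1.86-fold lower. Of the endocytosis genes, CAV1 had 31 reads against 0, AP2S1 was 2.35-fold higher, RAB5A and PICALM were each 1.71-fold lower.

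**Figure D2:**
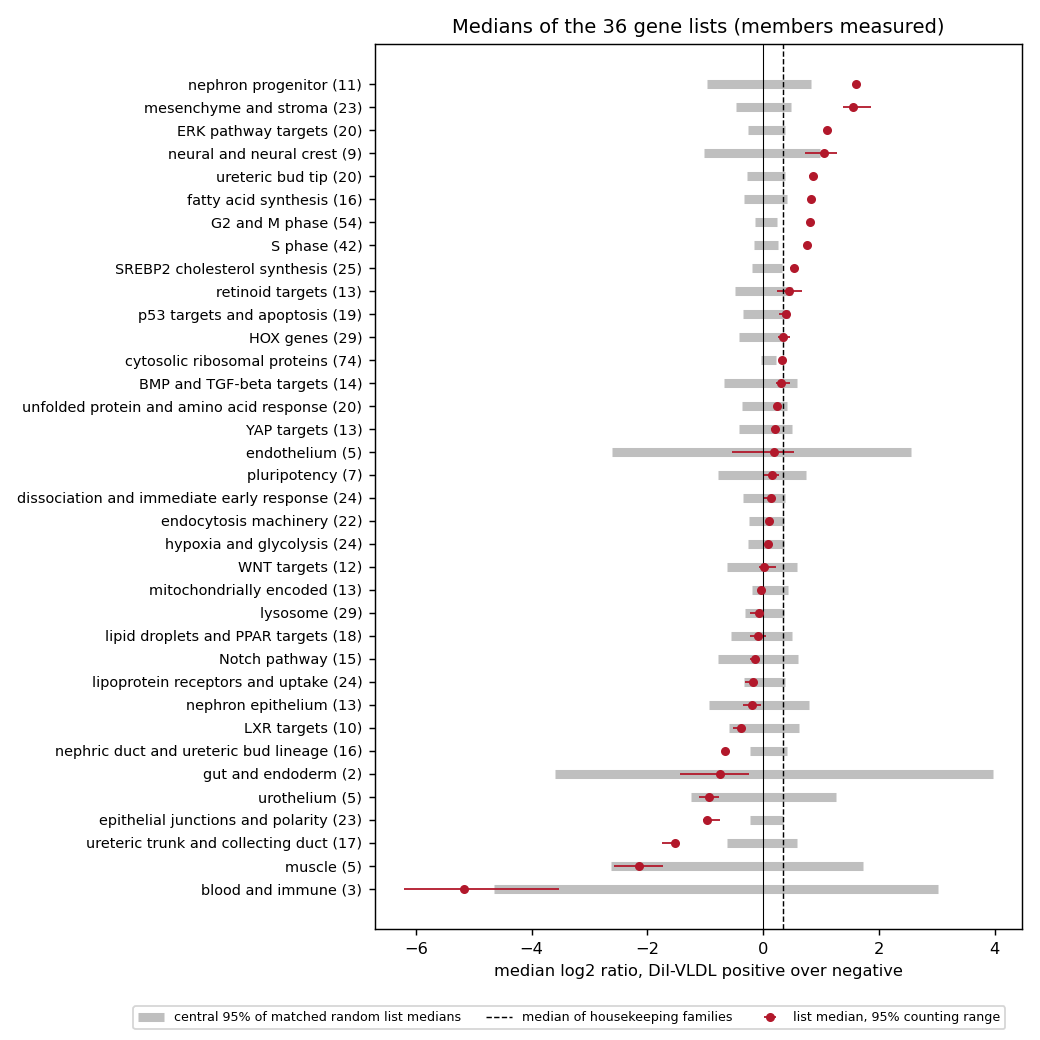
Median log2 ratio, DiI-VLDL positive over negative, of the 36 gene lists with the number of measured members in brackets; bars are 95% counting ranges and grey bands the central 95% of 10000 matched random lists. The dashed line is the median of the housekeeping families (0.34). The tip list (0.87) lies above its band and the trunk and collecting duct list (-1.52) below it.

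Markers of other cell types differed too. Mesenchyme and stroma genes had a median log2 ratio of 1.55 (counting range 1.38 to 1.87; percentile 100), with 17 of 23 at least 2-fold higher and 1 at least 2-fold lower. TAGLN, a smooth muscle protein, had 174 reads against 0, and FOXD1, a stromal transcription factor, had 49 against 0. Against the floor of 3 counts they were at least 83.8-fold and 23.6-fold higher, and the lower ends of their intervals lie below these bounds. VIM and COL1A2 had the lowest ratios, at 2.23-fold and 1.97-fold lower. The 5 members with a mean of at least 50 CPM, which include both, had a median of 1.17. Nephron progenitor genes had a median of 1.61 (percentile 99.95), with 7 of 11 at least 2-fold higher and 1 lower. GDNF, the ligand of RET, had 125 reads against 0 and was at least 60.2-fold higher against that floor (lower interval end 48.2). SIX2 had 75 reads against 0, SALL1 was 1.07-fold higher and OSR1 7.83-fold lower. Neural and neural crest genes had a median of 1.05 (percentile 98.0) but a mean log2 ratio of 0.04. Of 9 measured members, 5 were at least 2-fold higher and 2 at least 2-fold lower. NES was 3.19-fold and PAX6 3.37-fold higher, PAX3 3.05-fold lower. Over 12 alternatives this median ran from 0.06 to 1.67. Muscle genes (-2.15, percentile 5.54; 4 of 5 at least 2-fold lower) and urothelium genes (-0.93, percentile 5.81; 2 of 5) were lower but inside the range of matched lists, and the muscle median was 0.038 with no filter. Nephron epithelium (-0.19, percentile 35.5), endothelium (0.19, percentile 57.7), gut and endoderm (-0.74, percentile 38.2) and pluripotency genes (0.15, percentile 67.6) lay inside it. Of the blood and immune list 3 genes were measured, with a median of -5.17 (percentile 1.96; 0.67 at 10 CPM, where 1 gene is left), HBE1 and LYZ at 1 read each in the positive library and RUNX1 1.59-fold higher.

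The lists of RNA quality and stress lay inside the range of matched random lists. They do not show that the 2 RNA preparations were alike, since whole gene classes differed, as given at the end of this paragraph. Mitochondrially encoded genes took 2.34% of counts in the positive and 2.49% in the negative library, with a median log2 ratio of -0.04 (percentile 16.8; MT-ND3 2.57-fold and MT-CO3 1.19-fold higher, MT-ND6 3.21-fold and MT-ATP8 1.14-fold lower). The dissociation and immediate early response list had a median of 0.14 (percentile 75.1; EGR3 79 and NR4A2 54 reads against 0, BTG2 2.28-fold and FOSB 2.11-fold lower), p53 targets and apoptosis 0.40 (percentile 95.9; CDKN1A 4.51-fold and GDF15 3.69-fold higher, TP53INP1 1.45-fold and RRM2B 1.39-fold lower), the unfolded protein and amino acid response 0.24 (percentile 86.0; TRIB3 18.3-fold and SDF2L1 9.79-fold higher, ASNS 2.25-fold and DDIT4 2.72-fold lower) and hypoxia and glycolysis 0.08 (percentile 56.3; EGLN3 114 reads against 0, CA12 2.41-fold higher, NDRG1 9.87-fold and BNIP3 3.61-fold lower). MALAT1, a nuclear long noncoding RNA, was chosen for mention after its values were seen. It took 0.774% of counts in the positive and 2.45% in the negative library, 3.06-fold lower in the former (3.04 to 3.09). At a mean of at least 10 CPM, median log2 ratios were -0.60 for long intergenic noncoding, -0.61 for antisense and -0.998 for sense intronic genes. They were 0.06 for protein-coding genes and 0.19 for processed pseudogenes. Of 63 replication-dependent histone genes, 59 were at least 2-fold higher. Whether these class differences come from the sorted cells or from the 2 preparations was not tested.

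Among genes with a mean of at least 10 CPM, those with the highest lower bounds of the ratio were, in order, THEM6, NCBP2-AS2, HOXA5, BNC2, SHISA2, MRPL58, PIMREG, CHRNB4, CPED1, UNC5B, GPRIN1 and HAS2. THEM6 had 358 reads in the positive library and 0 in the negative one, and was at least 172-fold higher. Against that floor HOXA5 was at least 129-fold higher (lower interval end 104) and BNC2, a zinc finger gene, at least 128-fold higher (103). MRPL58, a mitochondrial ribosomal protein and so 1 of the housekeeping genes, had 361 reads against 4, a ratio of 130 (50.5 to 481). The netrin receptor UNC5B was 39.5-fold higher (25.9 to 63.6) and HAS2, a hyaluronan synthase, 30.9-fold higher (17.4 to 60.7). Those with the lowest upper bounds were TMEM176A, ELF5, AOC1, NUS1P2, LINC01266, PLXNA4, PQLC3, S100A10, KCTD16, LINC00645, SLC9A2 and SLC9A4. TMEM176A had 0 reads against 466 and was at least 107-fold lower against that floor (lower interval end 87.1). AOC1, diamine oxidase, was 58.7-fold lower (35.5 to 105), and the plexin PLXNA4 17.2-fold lower (15.1 to 19.6) from 246 against 6110 reads. NUS1P2 is a pseudogene and its count may include reads of its parent gene. On chromosomes, 53 genes had no read in the negative and at least 100 in the positive library, and 169 the reverse.

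In GRCh38 coordinates of the deposited table, RET (ENSG00000165731.18) spans chromosome 10, 43077027 to 43130351, on the plus strand, and WNT11 (ENSG00000085741.12) chromosome 11, 76186325 to 76210736, on the minus strand. VLDLR (ENSG00000147852.15) spans chromosome 9, 2621834 to 2660053, on the plus strand. All of them are annotated as protein-coding, and their values are sums over all exons.

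In the authors' deposited table, no gene had an adjusted p-value under 0.05 with DESeq2, and the smallest was 0.92. An unadjusted p under 0.05 was given to 1290 of 33149 genes by the authors' deposited table, 643 higher and 647 lower in positive cells. The authors' deposited table gives WNT11 a log2 fold change of 1.84 with a standard error of 0.90. For RET the authors' deposited table gives 0.79 (standard error 0.65). With 1 library per group, none of these standard errors or p-values measures a spread between replicates.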

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

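With 1 library per group, leaving out a library was not possible, and no paired analysis was possible because each group has 1 library. The alternatives of chromosome rows, protein-coding genes, 50 CPM, length and GC content, housekeeping scaling, and housekeeping or abundant random lists were chosen after seeing the data. The tip, trunk, SREBP2 and lipoprotein uptake medians kept their sign under all 12 alternatives run for each. Of 508 values of the key genes and the most extreme genes under alternatives, 1 had another sign (ETV4, scaled to the housekeeping families). Other list members were not rerun; those with a log2 ratio between 0 and 0.34, such as OCLN, CDCA2, SALL1 and MT-CO3, are not higher on the housekeeping scale, which shifts all genes by -0.34. Where a cause is not given it was not tested.

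The number of genes at least 2-fold higher was 5387 at a fold of 1.5, and 1553 higher and 2173 lower passed a fold of 4. It was 13364 higher and 6053 lower with no filter, 1221 and 983 at 10 CPM, 282 and 193 at 50 CPM, where fewer genes enter, and 2541 higher and 2101 lower among protein-coding genes alone, where the share of higher genes among both was 54.7% in place of 46.1%.

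The tip median was 0.78 corrected for length and GC content, 0.93 with the deeper library thinned, 0.95 at 10 CPM, 0.73 at 50 CPM and 0.52 on the housekeeping scale. The trunk median was -1.39 with log2(CPM + 1), -1.76 without shared members and -1.87 on the housekeeping scale. The SREBP2 median was 0.45 corrected for length and GC content, 0.46 on total counts without the most abundant genes and 0.19 on the housekeeping scale, with percentile 94.9 among housekeeping lists. The lipoprotein uptake median was -0.51 on the housekeeping scale, with percentile 0 among housekeeping lists. The ribosomal protein median became -0.015 on it. The blood and immune median turned to 0.67 at 10 and at 50 CPM, where 1 gene is left. Under at least 1 alternative other than that scale, the medians of 9 lists had another sign: WNT targets, blood and immune, dissociation response, gut and endoderm, lipid droplets, mitochondrially encoded, muscle (0.038 with no filter), nephron epithelium, and p53 targets. Of these, the blood and immune list alone lay outside the range of matched lists in the main analysis.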

Other observations

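The histone and gene type values, and the tests of the trunk list, of length and of GC content, were chosen after the results were seen. The housekeeping families were chosen after 2 of their members, MRPL58 and TIMM10, had been seen among the most extreme genes.

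Signalling target lists outside the ERK pathway lay inside the range of matched random lists. WNT targets had a median log2 ratio of 0.01 (percentile 54.4), with 4 of 12 at least 2-fold higher and 1 lower: DKK1, a secreted WNT inhibitor, was 22.3-fold higher from 77 against 5 reads, and NKD2 3.19-fold higher; RNF43, which removes WNT receptors from the surface, was 2.02-fold and its relative ZNRF3 1.87-fold lower. BMP and TGF-beta targets had a median of 0.31 (percentile 87.3; BAMBI 90 reads against 0, TGFBI 4.75-fold higher, LTBP2 1.63-fold and ID3 1.11-fold lower), retinoid targets 0.45 (percentile 96.2; RARRES2 45 reads against 0, HOXB1 2.52-fold and CYP26C1 1.68-fold lower), the Notch pathway -0.14 (percentile 33.1; DLL1 46 and DLL4 43 reads against 0, DTX1 3.42-fold and HEY1 2.26-fold lower) and YAP targets 0.20 (percentile 76.3; ANKRD1 43 reads against 0, AMOTL2 2.22-fold higher, AXL 3.06-fold and F3 2.20-fold lower). HOX genes had a median of 0.35 (percentile 96.7), with 11 of 29 at least 2-fold higher, among them HOXA5 and HOXD10 with no read in the negative library, and 3 at least 2-fold lower, among them HOXB13 with 83 reads in the negative and 0 in the positive library, and HOXC8, 3.04-fold lower.

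Replication-dependent histone genes were higher in the positive library: of 63 with a mean of at least 10 CPM, 59 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.79 (percentile 100). Their reads can be shared between near-identical copies. The S phase list had a smaller median (0.75). The libraries hold poly(A) RNA, and expression of these genes cannot be told apart here from differences between the 2 preparations. At the same minimum, 112 long intergenic noncoding genes had a median of -0.60 and 87 antisense genes -0.61, against 0.06 for 10613 protein-coding genes.

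Genes of low abundance lay far apart between the libraries, some with no read in 1 library and over 100 in the other. If few molecules per gene lay behind the reads, housekeeping genes would scatter as well, and at 10 to 30 CPM the robust SD of 118 of them was 6.84 times that of simulated counts. Differences between the sorted cells would leave housekeeping genes calmer than others. The share at least 2-fold apart was 28.0% for them and 31.6% for 3476 other protein-coding genes. The ratio of 0.88 (bootstrap interval over genes 0.62 to 1.15) does not decide. These shares were not centred, so the shift of the housekeeping genes (median log2 ratio 0.36 against 0.06 for the others) can raise theirs. Their robust SD, which that shift does not enter, was 0.80 against 0.96. Of the housekeeping genes apart, 32 were higher and 1 lower in the positive library, a 1-sided shift that even sampling of few molecules in both libraries does not by itself give. A median shift of like size was seen over all 395 housekeeping genes (0.34) and the ribosomal protein genes (0.33), so it is not particular to this abundance. Few sampled molecules may account for much of the scatter, but which library they affect more is not settled. Genes with 1 to 3 reads were fewer in the negative library (1321 against 5918). Yet 169 genes with at least 100 reads there had no read in the positive library, and 53 the reverse. True differences of low genes cannot be told apart from such scatter with 1 library each.

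Trunk and collecting duct genes were lower in the positive library. Scatter from few molecules would place their median inside the range of matched random lists, but it lay at percentile 0.01. That value is the one reported above, known before this comparison was chosen, and not a separate check. A trend on gene length and GC content was argued against as well, since the median after correction was -1.65. A difference between cells that did and did not take up DiI-VLDL, such as a lower share of trunk-like cells among positive cells, may account for it as a hypothesis, and it was not tested against differences between the 2 preparations. A lower share of bud epithelium as a whole stays open too, since lineage genes were lower (median -0.67) and mesenchyme (1.55) and nephron progenitor genes (1.61) higher, although tip genes were higher (0.87).

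Mesenchyme genes were higher in the positive library, and a second list with no gene of the first was written before its values were seen. Its 35 measured members had a median log2 ratio of 0.67 at percentile 99.99, which argues against scatter from few molecules as the whole cause. Mesenchymal cells in the positive gate may be a source: the 24 members with at least 50 CPM, which such cells would bring along, had a median of 0.57. Its bootstrap interval of 0.36 to 0.83 resamples these genes within 1 pair of libraries and measures no spread between sorts. The lower end lies close to the 0.34 of the housekeeping families, which is taken over all abundances. The 5 such members of the first list had a median of 1.17. Against mesenchymal cells as the source stand abundant genes that were lower, chosen after their values were seen. They are VIM and COL1A2 of the first list and BICC1, IGFBP3, SPARC, COL4A1 and COL4A2 of the second. However, 30 of the 35 second-list genes reach 10 CPM in the negative library, so that the bud cells themselves may express them. A mesenchymal program within ureteric bud cells that take up the lipoprotein stays open as well and was not tested; the sort as described names no marker other than DiI-VLDL and DAPI.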
